A study of Sus scrofa with 9 samples.

How the data were processed

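Mammary gland biopsies had been taken from 6 Large White sows on days -17, 1 and 17 relative to parturition, per the labels. Total RNA of 2 sows at a time had been pooled in equal volumes, labelled with biotin and hybridized to Affymetrix porcine GeneChips, which gave 9 arrays, 3 pools on each of 3 days. The deposited values are intensities: 1 linear signal intensity per probe set and array, made with MAS5 per the submitters' processing notes and not on a log scale. The version of MAS5 was not stated. On every array the mean signal after trimming 2% at each end lay between 500.088 and 500.112, so the arrays share 1 scaled mean. No value was 0 or negative.

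Of the 24123 probe sets, 124 Affymetrix control probe sets were left out of the tests and 23999 were kept as endogenous, among them 64 reporter probe sets, of which 2 passed the filter. A probe set was tested if its signal was at or above the 40th percentile of the array in at least 3 of the 9 arrays, which kept 15519. Gene symbols came from the platform annotation: 10099 probe sets had 1 symbol, 198 had several and were not assigned to a gene, and 13826 had none here. Genes with several tested probe sets (1406 of 5670) were represented by the probe set with the highest mean log2 signal. Signals were taken to log2 with no pseudocount.

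All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, residual degrees of freedom with the prior 10.3), with day as the only term. The 3 comparisons were day 1 against day -17, day 17 against day 1 and day 17 against day -17, each two-sided, beside an F test over the 3 days. P values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. An exact test of 3 against 3 values cannot give a p under 0.1, so no single gene was tested that way. The code was tested on simulated data with the same layout: of 100 probe sets simulated with a 2-fold change, 52, 40 and 40 were called in the 3 comparisons, and of 100 with a 4-fold change 83, 86 and 77. Of the calls, 4.26%, 7.35% and 5.65% were false.

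Pools carry the numbers 1 to 3 on each day, and whether a number stands for the same sows is not stated. Checked were the correlations, across probe sets, of samples' deviations from their day's mean. For day 1 against day -17, samples with the same number had correlations of 0.235 to 0.506 and others -0.387 to 0.113. For day 17 against day -17 these were 0.105 to 0.130 and -0.0739 to -0.0421. In both, all 3 pairs exceeded 0.1. The number was used as a block only in alternatives.

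Gene lists were fixed before the data were examined: 29 lists of milk synthesis functions, general functions and cell type markers, which share no gene. List symbols absent from the annotation were looked up as older names in the RefSeq gene table. The 25 lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera compares a list with the other genes, whereas fry tests whether a list's genes move, on balance, in 1 direction. The lists of neutrophil, erythrocyte, skeletal muscle and skin keratinocyte markers were too short.

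The rule for naming genes was also fixed before the data were examined. It took the 6 largest rises and 6 largest falls past the threshold (4 and 4 for day 17 against day -17) among genes whose 3 values on 1 day all lay above the other 3, leaving out uncharacterised locus names. From each list with a called gene it took the 2 called genes with the largest change in the majority direction and 1 in the other (1 and 1 for day 17 against day -17). From a list without one, it took the gene with the smallest p. Genes named outside the rule are said to have been chosen after their values were seen.

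Alternatives chosen before the data were examined were quantile normalization, median centring, a pseudocount of 16, no filter, a stricter filter (60th percentile), no intensity trend, a fit of the 6 compared samples alone and the pool number as a fixed or random block. Each array was also left out in turn. For the counts, a minimum fold of 2 and a single probe set per gene were tried, and for genes and lists a mean over a gene's probe sets. Scaling each array to its 21 E. coli control probe sets was added after seeing the data, as were 9 gene families and 7 of the 11 tests of explanations. Splits of the samples into groups, 10 for each comparison and 100 for the 3 days, the real one included, were counted. The expected overlap of comparisons with a shared day was simulated 20 times without effects.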

Results

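Gene expression was measured in the mammary gland of Large White sows at 3 stages of reproduction: 17 days before farrowing (day -17), 1 day after it (day 1) and 17 days after it (day 17). Each of 6 sows was biopsied on all 3 days. The total RNA of 2 sows was pooled in equal volumes for each array, which gave 3 pools per day and 9 pooled samples on Affymetrix porcine GeneChips. Arrays have no sequencing depth, and their number limits the precision. Signals of the 23999 endogenous probe sets ranged from 0.0632 to 83677, and pools of the same day had Spearman correlations of 0.954 to 0.976 across probe sets, which are not independent replicates. After dim probe sets were left out, 15519 were tested, and 5670 genes had at least 1 of them. Unless another measure is named, a gene is given as its log2 difference ± standard error in limma, with n = 3 pools per day, from its probe set with the highest mean log2 signal, and a list by the median log2 difference of its genes.

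The 3 days differed widely. In a limma F test, 7028 of the 15519 probe sets (45.3%) differed among the days. Of 7 milk protein genes, 6 were brighter on day 1 and 7 on day 17 than on day -17, and of 10 milk fat globule genes 9 and 9. Of 23 cell cycle genes, 16 were dimmer on day 17 than on day 1, and 17 were dimmer than on day -17. Of 26 fibroblast matrix genes, 15 were dimmer on day 17 than on day -17. These lists shifted by camera, which sets a list against the other genes, at a preset correlation but not with an estimated one (adjusted p from 0.144 to 0.621). Directions are relative to each array's trimmed mean signal, to which the deposited values had been scaled. The 21 probe sets for E. coli transcripts, which are meant to be added in fixed amounts before hybridization, were brighter by a median of 0.44 log2 on day 1 than on day -17 and by 1.28 on day 17. Scaling the arrays to these controls (E. coli scaling), an alternative chosen after seeing the data, lowered all log2 differences by 0.43, 0.87 and 1.30 for day 1 against day -17, day 17 against day 1 and day 17 against day -17. The median over all tested probe sets then moved from -0.07, -0.0092 and -0.08 to -0.49, -0.88 and -1.38.

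**Figure D1:**
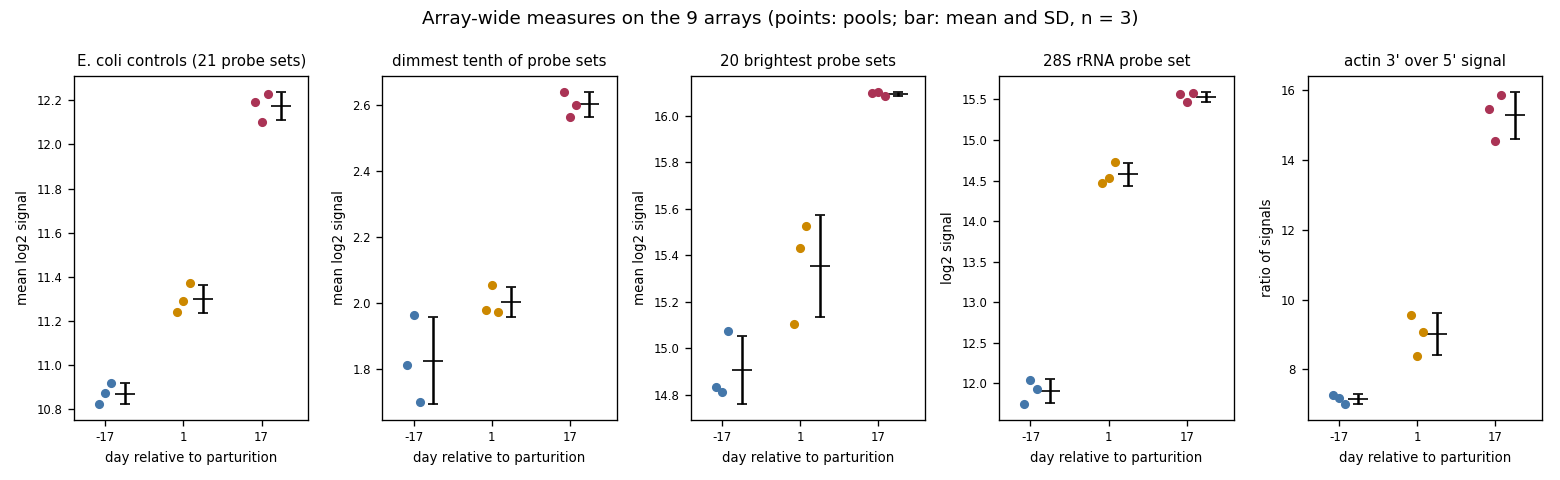
Measures of each array (vertical axes, log2 signal, or a ratio of 3' to 5' signal for actin) by day relative to parturition (horizontal axis), with a point per pooled sample and a bar for mean and SD, n = 3. The mean log2 signal of the 20 brightest endogenous probe sets went from 14.91 on day -17 to 16.10 on day 17 and that of the E. coli controls from 10.87 to 12.17.

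**Figure D2:**
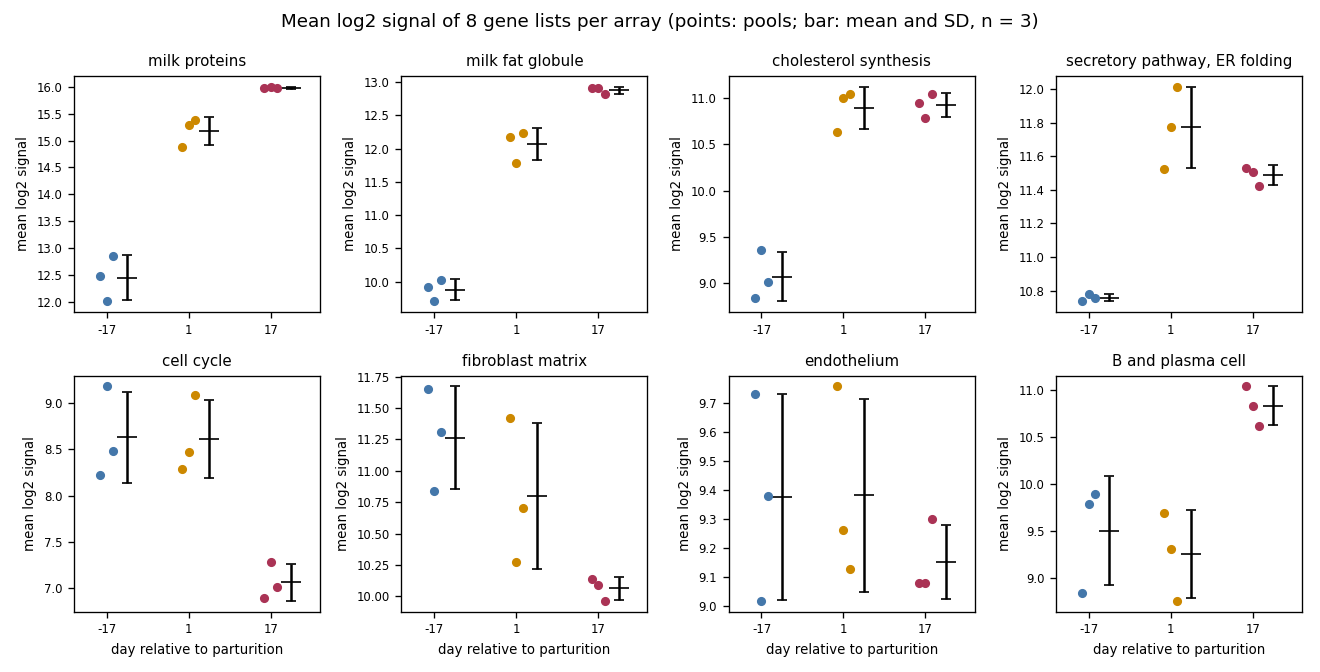
Mean log2 signal (vertical axis) of 8 gene lists by day relative to parturition (horizontal axis), with a point per pooled sample and a bar for mean and SD, n = 3. All 3 day 17 points lie above all day -17 points for milk proteins, the milk fat globule, cholesterol synthesis, the secretory pathway and B and plasma cells, and below them for the cell cycle and fibroblast matrix, although with E. coli scaling the secretory pathway median for these days turned from 0.77 to -0.53.

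The first comparison asked how the gland on the day after farrowing differed from late pregnancy. WAP, which encodes whey acidic protein, rose 42.5-fold (log2 difference 5.41 ± 0.23, n = 3 pools per day), from a signal of 980.0 ± 393 (SD) on day -17 to 39886 ± 6058 on day 1. LALBA, which encodes alpha-lactalbumin, the regulatory part of lactose synthase, rose 35.5-fold (5.15 ± 0.30), from 1316 ± 668 to 43436 ± 8515. ACSL6, a long-chain acyl-CoA synthetase, rose by 7.43 ± 0.29 and HP, the haemoglobin-binding acute phase protein haptoglobin, by 7.52 ± 0.39, both from a dim day -17 signal (140.1-fold for ACSL6 and 143-fold for HP with a pseudocount of 16). DGAT2, a diacylglycerol acyltransferase, and CA3, a carbonic anhydrase abundant in fat and muscle, fell (-3.80 ± 0.53 and -4.97 ± 0.86).

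By limma, 3736 of 15519 probe sets (24.1%) changed at an adjusted p of 0.05, 1860 of them higher and 1876 lower on day 1. Among these, 1592 changed at least 2-fold and 1852 had no gene symbol here. The 3 values of one day all lay above those of the other for 40.8% of the tested probe sets, where chance gives 10%. The split between higher and lower depended on the scaling: centring each array on its median gave 2474 higher and 1174 lower, and E. coli scaling gave 814 and 6271. The count was 2324 without day -17 pool 3 and 2110 without day 1 pool 3. Of 25 gene lists tested by camera with a preset correlation, 11 shifted, 9 up and 2 down. With an estimated correlation 0 shifted, while 5 had an unadjusted p under 0.05, and fry gave 8.

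The other largest rises to day 1 were EDDM3B (8.08 ± 0.40), MUC4 (6.79 ± 0.26), SLC6A14 (6.71 ± 0.62) and the open reading frame C7H6orf52 (6.18 ± 0.60). All 4 lay below the filter level on day -17. With a pseudocount of 16 the folds were 45.2 for EDDM3B, 67.4 for MUC4, 49.3 for SLC6A14 and 6.02 for C7H6orf52. The other largest falls were CYP2A19, a cytochrome P450 (-6.58 ± 0.96, fold 31.8 with that pseudocount), PON3, a lactonase (-3.82 ± 0.67), RBP4, a retinol carrier (-3.55 ± 0.88), and ALDOC, an aldolase (-3.26 ± 0.56). CYP2A19 and PON3 were dim on day 1, and the call of RBP4 ended without day -17 pool 1 (adjusted p = 0.0648) or day -17 pool 3 (0.0573).

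Of the 7 measured milk protein genes, 6 rose, 0 fell and 1 did not pass (6 and 0 adjusted over the list alone, 5 and 0 with E. coli scaling), with median 1.81, camera adjusted p = 5.08e-07, and adjusted p = 0.219 with an estimated correlation. The rises spanned CSN1S1, an alpha casein, at 0.68 ± 0.12 and WAP at 5.41 ± 0.23. PAEP, beta-lactoglobulin, did not pass (0.30 ± 0.17). CSN1S1 and PAEP were named after their values were seen. On day 1 WAP stood at 67.7% and LALBA at 73.7% of the brightest endogenous probe set, near the range's top. Saturation could not be tested and would make changes in this list too small, while E. coli scaling lowered each by 0.43. In lactose synthesis, B4GALT1, the catalytic part of lactose synthase, rose by 2.66 ± 0.16 and UGP2, which makes UDP-glucose, by 1.88 ± 0.17. HK1, a hexokinase, fell (-0.54 ± 0.13), lost without day -17 pool 3 (adjusted p = 0.0569). That list did not shift: 2 rose and 1 fell of 12 (3 and 3 adjusted over the list alone, 2 and 6 with E. coli scaling, median -0.14, camera adjusted p = 0.843), and its mean of 0.13 differed in sign from its median and its test.

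Of the 10 measured milk fat globule genes, 9 rose, 1 fell and 0 did not pass (9 and 1 adjusted over the list alone, 8 and 1 with E. coli scaling), with median 1.79, camera adjusted p = 8.72e-07, and adjusted p = 0.144 with an estimated correlation. MUC4 and MUC1, mucins of the apical membrane, rose by 6.79 ± 0.26 and 3.48 ± 0.28, and VAMP2, a vesicle fusion protein, fell (-0.88 ± 0.21, lost without day -17 pool 3 (adjusted p = 0.0626) or day 1 pool 3 (0.062)). Of the 12 measured genes of cholesterol synthesis, 11 rose, 0 fell and 1 did not pass (11 and 0 adjusted over the list alone, 10 and 0 with E. coli scaling), with median 1.77, camera adjusted p = 7.21e-09, and adjusted p = 0.181 with an estimated correlation. HMGCS1, an early enzyme of the pathway, rose by 3.66 ± 0.28 and HSD17B7, a late enzyme, by 3.29 ± 0.45.

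Of the 27 measured genes of fatty acid and triglyceride synthesis, 11 rose, 3 fell and 13 did not pass (12 and 3 adjusted over the list alone, 9 and 5 with E. coli scaling), with median 0.46, camera adjusted p = 0.00517, and adjusted p = 0.438 with an estimated correlation. This call was lost without day -17 pool 2 (adjusted p = 0.0646). ACSL3, an acyl-CoA synthetase, rose by 3.59 ± 0.16 and INSIG1, a sterol-regulated retention factor of the endoplasmic reticulum, by 2.96 ± 0.22. The 3 members that fell were DGAT2 (-3.80 ± 0.53) and, named after their values were seen, ME1, the cytosolic malic enzyme (-3.06 ± 0.62), and ACSL1 (-1.41 ± 0.38, lost without day -17 pool 1 (adjusted p = 0.0727), day -17 pool 3 (0.0803), day 1 pool 2 (0.0698) or day 1 pool 3 (0.0941)). Beside them, adipocyte markers had a median log2 difference of -0.90, and of 11, 0 rose and 2 fell (0 and 1 adjusted over the list alone): RBP4 (-3.55 ± 0.88) and GPD1 (-1.95 ± 0.61, lost without day -17 pool 1 (adjusted p = 0.134), day -17 pool 3 (0.132), day 1 pool 2 (0.133), day 1 pool 3 (0.129), day 17 pool 1 (0.0582), day 17 pool 2 (0.0523) or day 17 pool 3 (0.0559) and after quantile normalization (0.0634), after median centring (0.0557), with no filter (0.057), without an intensity trend (0.0603) or with the 6 samples alone (0.0761)). The adipocyte list itself did not shift (camera adjusted p = 0.141), but did without day -17 pool 2 (adjusted p = 0.00918) or day 1 pool 1 (0.0187) and after median centring (0.0438).

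Of the 37 measured genes of the secretory pathway and of protein folding in the endoplasmic reticulum, 31 rose, 1 fell and 5 did not pass (33 and 1 adjusted over the list alone, 21 and 2 with E. coli scaling), with median 0.97, camera adjusted p = 1.4e-14, and adjusted p = 0.209 with an estimated correlation. SDF2L1 and CRELD2, both induced when unfolded protein accumulates there, rose by 2.74 ± 0.50 and 2.49 ± 0.29. DDIT3, a stress-induced transcription factor, fell (-0.59 ± 0.17, lost without day -17 pool 1 (adjusted p = 0.104), day -17 pool 3 (0.0736), day 1 pool 2 (0.104) or day 1 pool 3 (0.0837) and after quantile normalization (0.086), after median centring (0.0824), with no filter (0.0533) or with the 6 samples alone (0.0658)). Of the 14 measured amino acid transporters, 6 rose, 0 fell and 8 did not pass (6 and 0 adjusted over the list alone, 1 and 1 with E. coli scaling), with median 0.76, camera adjusted p = 0.0111, and adjusted p = 0.144 with an estimated correlation. SLC6A14, a carrier of neutral and cationic amino acids, led them, and SLC7A4 (1.29 ± 0.38) was lost without day -17 pool 1 (adjusted p = 0.1), day -17 pool 2 (0.0565), day -17 pool 3 (0.0526), day 1 pool 2 (0.121), day 17 pool 2 (0.0504) or day 17 pool 3 (0.0519) and with no filter (0.0512), with the 6 samples alone (0.0761) or with E. coli scaling (0.089, log2 0.86). Of the 9 measured ion transport genes, 4 rose, 0 fell and 5 did not pass (5 and 1 adjusted over the list alone, 4 and 2 with E. coli scaling), with median 0.51, camera adjusted p = 0.0111, and adjusted p = 0.144 with an estimated correlation. SLC34A2, a sodium phosphate cotransporter, rose by 4.08 ± 0.26 and ORAI1, a calcium channel, by 2.37 ± 0.17.

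Of the 18 measured genes of the acute phase and secreted defence, 8 rose, 0 fell and 10 did not pass (9 and 3 adjusted over the list alone, 6 and 4 with E. coli scaling), with median 0.44, camera adjusted p = 0.0111, and adjusted p = 0.144 with an estimated correlation. HP and LBP, which binds bacterial lipopolysaccharide (5.39 ± 0.28, dim on day -17), led them. PGLYRP1, which binds bacterial peptidoglycan, rose by 4.57 ± 0.20, from 999 to 23443. It was the only 1 of the 4 measured neutrophil markers that passed (1 and 0 adjusted over the list alone, median log2 difference 0.46), in a list too short for a test. Of the 9 measured MHC class II genes, 1 rose, 5 fell and 3 did not pass (1 and 5 adjusted over the list alone, 0 and 6 with E. coli scaling), with median -0.59, camera adjusted p = 0.0443, and adjusted p = 0.804 with an estimated correlation. SLA-DQB1 fell (-1.11 ± 0.23), as did SLA-DRB1 (-1.06 ± 0.17), both chains of antigen-presenting molecules. SLA-DMA, which loads peptides onto these, rose (0.75 ± 0.20, lost without day -17 pool 1 (adjusted p = 0.0718), day -17 pool 2 (0.063) or day 1 pool 3 (0.0903) and with E. coli scaling (0.159, log2 0.32)). The shift of this list was lost without day -17 pool 2 (adjusted p = 0.0684), day -17 pool 3 (0.0744), day 1 pool 2 (0.134), day 1 pool 3 (0.0927), day 17 pool 1 (0.0549), day 17 pool 2 (0.0564) or day 17 pool 3 (0.0514) and with the 6 samples alone (0.0684), with the pool number as a fixed block (0.0789), with it as a random block (0.0526), with E. coli scaling (0.289, median -1.02) or by fry (0.0986).

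Of the 26 measured fibroblast matrix genes, 1 rose, 3 fell and 22 did not pass (1 and 3 adjusted over the list alone, 0 and 12 with E. coli scaling), with median -0.41, camera adjusted p = 0.0251, and adjusted p = 0.904 with an estimated correlation. LUM, a collagen-binding proteoglycan, fell (-1.11 ± 0.26), THY1 fell (-1.40 ± 0.40, lost without day -17 pool 1 (adjusted p = 0.0843), day -17 pool 3 (0.0873), day 1 pool 2 (0.0706) or day 1 pool 3 (0.0921) and without an intensity trend (0.0534) or with the 6 samples alone (0.0734)), and the protease inhibitor TIMP1 rose (0.59 ± 0.16, lost without day -17 pool 2 (adjusted p = 0.0715), day -17 pool 3 (0.0951) or day 1 pool 3 (0.0961) and with the 6 samples alone (0.0568) or with E. coli scaling (0.459, log2 0.16)). The shift of the list was lost without day -17 pool 1 (adjusted p = 0.222) or day 1 pool 2 (0.262) and with E. coli scaling (0.308, median -0.84) or by fry (0.344). Of the 56 measured ribosomal protein genes, 1 rose, 2 fell and 53 did not pass (0 and 0 adjusted over the list alone, 0 and 25 with E. coli scaling), with median 0.16, camera adjusted p = 0.0419, and adjusted p = 0.918 with an estimated correlation and the opposite direction after quantile normalization (median -0.13) or E. coli scaling (-0.27). That call was also lost without day -17 pool 1 (adjusted p = 0.2), day -17 pool 2 (0.129), day 1 pool 2 (0.465), day 1 pool 3 (0.182), day 17 pool 2 (0.052) or day 17 pool 3 (0.0514) and with a stricter filter (0.0711), with the 6 samples alone (0.0649), by fry (0.386) or with a mean over its genes' probe sets (0.177).

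Among markers of other cell types, the endothelial list did not shift: 0 rose and 1 fell of 12 (0 and 0 adjusted over the list alone, 0 and 3 with E. coli scaling, median 0.15, camera adjusted p = 0.883). Its 1 member that fell was VWF (-1.11 ± 0.34), whose other probe set had the opposite sign and whose call was lost without day -17 pool 1 (adjusted p = 0.1), day -17 pool 3 (0.107), day 1 pool 2 (0.121), day 1 pool 3 (0.138), day 17 pool 1 (0.0505), day 17 pool 2 (0.0526) or day 17 pool 3 (0.0562) and after quantile normalization (0.0516), after median centring (0.0599), without an intensity trend (0.0599), with the 6 samples alone (0.0778) or with a mean over its probe sets (0.158). Luminal epithelial genes went both ways: 5 rose and 2 fell of 17 (5 and 4 adjusted over the list alone, 4 and 5 with E. coli scaling, median 0.16, camera adjusted p = 0.703), with a mean of -0.02 against that median. The junction protein CLDN3 rose (1.83 ± 0.29), as did the secreted iron-binding protein LTF (1.44 ± 0.27), and the transcription factor FOXA1 fell (-2.50 ± 0.65, lost without day -17 pool 2 (adjusted p = 0.0734), day -17 pool 3 (0.0784) or day 1 pool 3 (0.0721)). For myoepithelium and smooth muscle, 2 rose and 0 fell of 12 (2 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 0.141). The contractile genes ACTG2 (2.04 ± 0.30) and MYL9 (1.31 ± 0.18) rose, although the other probe set of ACTG2 had the opposite sign, and this list shifted without day 1 pool 3 (adjusted p = 0.036).

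For T and NK cell markers, 0 rose and 2 fell of 8 (0 and 2 adjusted over the list alone, 0 and 3 with E. coli scaling, median -0.62, camera adjusted p = 0.106), with a shift without day 1 pool 1 (adjusted p = 0.0137) and after median centring (0.0427). Their 2 falls were CD8A (-1.34 ± 0.32, lost without day -17 pool 2 (adjusted p = 0.0563)) and KLRK1 (-1.39 ± 0.39, lost without day -17 pool 2 (adjusted p = 0.0911), day -17 pool 3 (0.102), day 1 pool 2 (0.0844) or day 1 pool 3 (0.0932) and with the 6 samples alone (0.0512)), both dim on day 1. For macrophage markers, 1 rose and 0 fell of 11 (1 and 0 adjusted over the list alone, 0 and 5 with E. coli scaling, median -0.26, camera adjusted p = 0.654), with a shift without day 1 pool 1 (adjusted p = 0.0187). Their rise was CD14 (1.08 ± 0.26, lost without day 1 pool 2 (adjusted p = 0.0548) and with E. coli scaling (0.0703, log2 0.65)). For B and plasma cell markers, 0 rose and 0 fell of 5 (0 and 0 adjusted over the list alone, 0 and 2 with E. coli scaling, median 0.10, camera adjusted p = 0.654), with a mean of -0.25 and a downward test against that median. For interferon response genes, 0 rose and 1 fell of 18 (0 and 1 adjusted over the list alone, 0 and 5 with E. coli scaling, median -0.17, camera adjusted p = 0.525), with a shift without day -17 pool 2 (adjusted p = 0.0481). Of the 4 measured erythrocyte markers, HBB, a haemoglobin chain, fell (-0.91 ± 0.13) and the others did not pass (0 and 1 adjusted over the list alone). Of 2 skeletal muscle markers, TNNI2 fell (-1.59 ± 0.49, lost without day -17 pool 2 (adjusted p = 0.133), day -17 pool 3 (0.104), day 1 pool 1 (0.0866), day 1 pool 3 (0.0665) or day 17 pool 3 (0.0552) and after quantile normalization (0.0578), after median centring (0.0521), with no filter (0.0537), without an intensity trend (0.0518) or with the 6 samples alone (0.0631)), with 0 and 1 adjusted over the list alone. The only measured skin keratinocyte marker, KRT10, did not pass (0.22 ± 0.18).

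Cell cycle genes did not shift as a list between these days: 1 rose and 1 fell of 23 (1 and 1 adjusted over the list alone, 1 and 3 with E. coli scaling, median -0.07, camera adjusted p = 0.703). CKS2, a partner of cyclin-dependent kinases, rose (1.29 ± 0.26), and RRM1 fell (-0.71 ± 0.19, lost without day -17 pool 2 (adjusted p = 0.0797), day -17 pool 3 (0.0853) or day 1 pool 2 (0.0791) and after median centring (0.0576) or with the 6 samples alone (0.0508)). For mitochondrial energy genes, 7 rose and 1 fell of 36 (8 and 1 adjusted over the list alone, 2 and 14 with E. coli scaling, median 0.19, camera adjusted p = 0.0665), with a shift without day -17 pool 3 (adjusted p = 0.0217) or day 1 pool 1 (0.013) and after median centring (0.0281) or with no filter (0.044). ATP5G1, an ATP synthase subunit, rose by 1.38 ± 0.15 and CYCS, cytochrome c, by 1.07 ± 0.16. For prolactin and hormone signalling, 3 rose and 3 fell of 16 (3 and 3 adjusted over the list alone, 1 and 8 with E. coli scaling, median -0.54, camera adjusted p = 0.688), with a mean of the other sign (0.05). EGF, a growth factor also secreted in milk, rose by 5.05 ± 0.32, from a dim day -17 signal of 80.4 to 2832. For apoptosis and involution, 7 rose and 0 fell of 23 (9 and 2 adjusted over the list alone, 0 and 11 with E. coli scaling, median 0.03, camera adjusted p = 0.696), with TGFB1, a growth inhibitor of many epithelia, up (0.64 ± 0.14, lost with E. coli scaling (adjusted p = 0.304, log2 0.21) or with a mean over its probe sets (0.117)). Of the cell junction genes, OCLN, a tight junction protein, rose (1.06 ± 0.19), and for that list 1 rose and 0 fell of 8 (1 and 0 adjusted over the list alone, 1 and 2 with E. coli scaling, median -0.32, camera adjusted p = 0.688). The ratio of 3' to 5' signal of the actin control was 7.15 ± 0.13 on day -17 and 9.01 ± 0.59 on day 1 (SD), while that of GAPDH was 2.83 ± 0.39 and 2.29 ± 0.04.

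**Figure D3:**
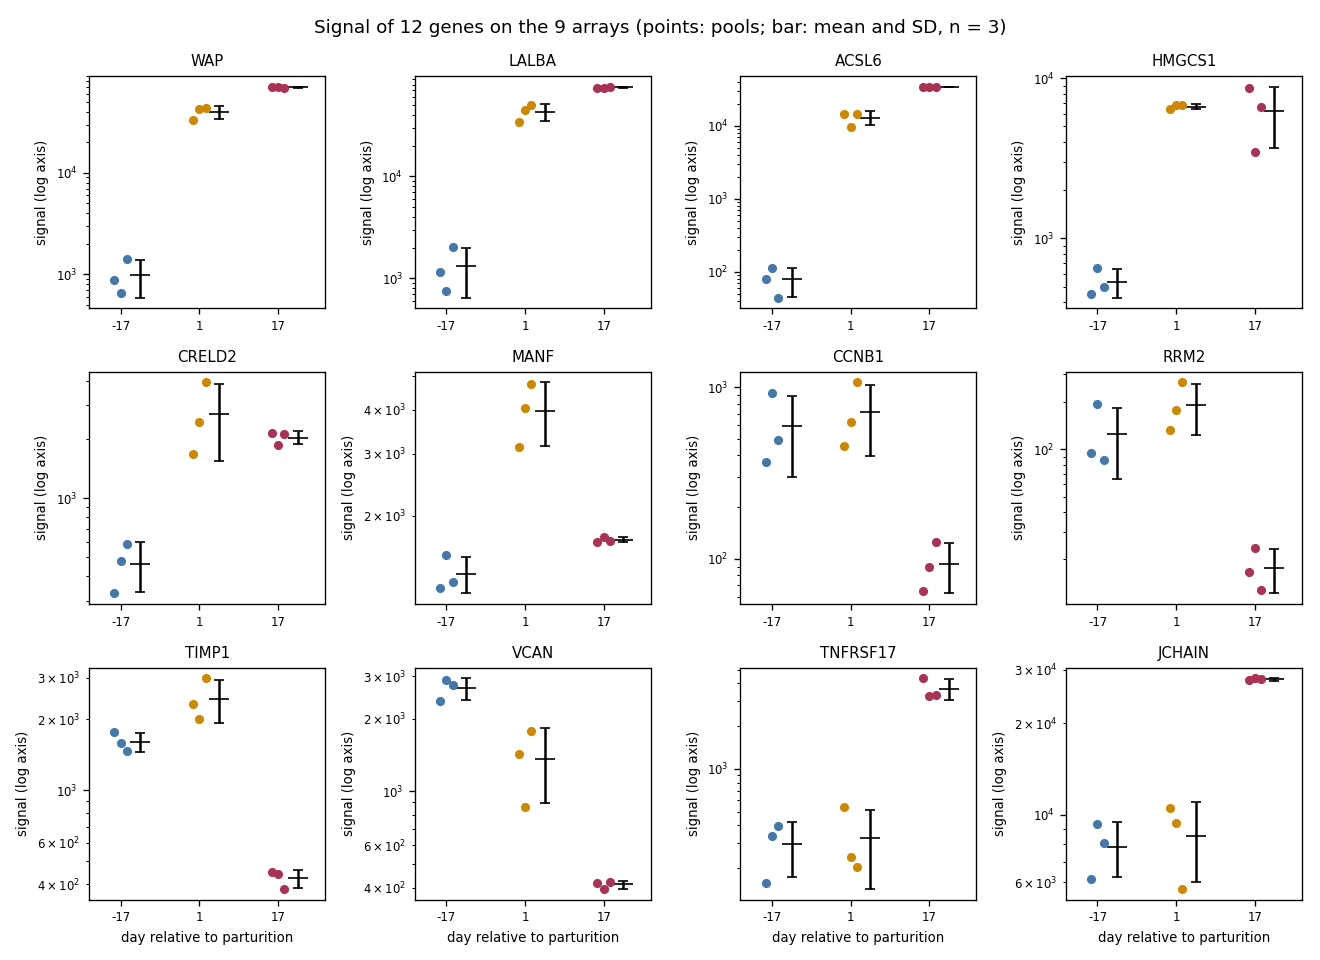
Signal (vertical axis, logarithmic, array units) of 12 genes by day relative to parturition (horizontal axis), with a point per pooled sample and a bar for mean and SD, n = 3. The 3 day 1 values of WAP, LALBA, ACSL6, HMGCS1 and CRELD2 lie above their day -17 values, and the 3 day 17 values of CCNB1, RRM2, MANF and TIMP1 lie below those of day 1.

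The second comparison asked how established lactation on day 17 differed from its first day. Among genes of the dividing cell, CCNB1, the cyclin that drives entry into mitosis, fell by 2.90 ± 0.40 on the log2 scale (n = 3 pools per day), from a signal of 715 ± 316 (SD) to 92.9 ± 30.1, and RRM2, a ribonucleotide reductase subunit, fell by 3.43 ± 0.45. PTHLH, which encodes parathyroid hormone-related protein, rose 17.8-fold (4.15 ± 0.45), from 74.2 ± 45.4 to 1285 ± 697. TNFRSF17, a receptor of plasma cells, rose 12.2-fold (3.60 ± 0.40). TIMP1 fell (-2.50 ± 0.16), and so did MANF, a folding factor of the endoplasmic reticulum (-1.20 ± 0.16).

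By limma, 2116 of 15519 probe sets (13.6%) changed, 1090 higher and 1026 lower on day 17. Among these, 820 changed at least 2-fold and 941 had no gene symbol here. The 3 values of one day all lay above those of the other for 34.7% of the tested probe sets, where chance gives 10%. Scaling to the E. coli controls gave 112 higher and 11002 lower. The count was 1397 without day 1 pool 2, 1329 without day 1 pool 3, 1079 without day 17 pool 1, 1168 without day 17 pool 2 and 1049 without day 17 pool 3. Of 25 gene lists, 8 shifted by camera, 5 up and 3 down. With an estimated correlation 0 shifted, while 1 had an unadjusted p under 0.05, and fry gave 5.

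The other largest rises were CRHR1, a receptor of corticotropin-releasing hormone (3.35 ± 0.59), MYLK, myosin light chain kinase (3.50 ± 0.98), CA11, a protein related to the carbonic anhydrases (3.20 ± 0.69), and P14ARF (2.92 ± 0.70). PTHLH, CRHR1, MYLK and CA11 were dim on day 1, and with a pseudocount of 16 their folds were 14.3, 4.47, 4.91 and 4.55. MYLK was lost without day 1 pool 1 (adjusted p = 0.0767), day 1 pool 2 (0.0793), day 1 pool 3 (0.0571), day 17 pool 1 (0.103), day 17 pool 2 (0.13) or day 17 pool 3 (0.138) and after quantile normalization (0.0534) or with a mean over its probe sets (0.0596). CA11 was lost without day 17 pool 1 (adjusted p = 0.0528) or day 17 pool 3 (0.0571), and P14ARF was lost without day 1 pool 1 (adjusted p = 0.0522), day 17 pool 1 (0.066), day 17 pool 2 (0.0759) or day 17 pool 3 (0.0604).

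The other largest falls were AOAH, which deacylates bacterial lipopolysaccharide (-4.36 ± 0.61), AGT, angiotensinogen (-3.94 ± 1.08), SKA1, a kinetochore protein (-3.64 ± 0.72), CES1, a carboxylesterase (-3.39 ± 0.60), and SLC46A2 (-3.39 ± 0.59). These 5 and RRM2 were dim on day 17, and with a pseudocount of 16 the folds were 15.3, 11.6, 4.55, 4.39 and 5.22, and 6.03 for RRM2. AGT was lost without any 1 of 6 arrays (adjusted p from 0.0545 to 0.11) and without an intensity trend (0.0626).

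Of the 23 measured cell cycle genes, 0 rose, 16 fell and 7 did not pass (0 and 19 adjusted over the list alone, 0 and 23 with E. coli scaling), with median -1.61, camera adjusted p = 7.25e-10, and adjusted p = 0.621 with an estimated correlation. All 23 had a negative log2 difference, between -3.43 for RRM2 and -0.41 for BIRC5, which was named after its values were seen. Of the 37 measured genes of the secretory pathway and protein folding, 0 rose, 10 fell and 27 did not pass (2 and 15 adjusted over the list alone, 0 and 37 with E. coli scaling), with median -0.30, camera adjusted p = 0.017, and adjusted p = 0.822 with an estimated correlation and a loss without day 1 pool 3 (adjusted p = 0.174) and by fry (0.232). MANF led the falls. PDIA4, a disulfide isomerase, fell by 0.91 ± 0.21, lost without any 1 of 4 arrays (adjusted p from 0.0622 to 0.0831). Of the 26 measured fibroblast matrix genes, 0 rose, 4 fell and 22 did not pass (0 and 8 adjusted over the list alone, 0 and 22 with E. coli scaling), with median -0.77, camera adjusted p = 0.000512, and adjusted p = 0.789 with an estimated correlation. TIMP1 and TNC, the matrix glycoprotein tenascin C (-2.12 ± 0.39, dim on day 17), fell most. The shift of that list was lost without day 1 pool 1 (adjusted p = 0.0563) and with E. coli scaling (0.549, median -1.64) or by fry (0.0985). Beside it, endothelial markers did not shift: 0 rose and 1 fell of 12 (0 and 1 adjusted over the list alone, 0 and 11 with E. coli scaling, median -0.17, camera adjusted p = 0.414), with a fall of the receptor TIE1 (-1.15 ± 0.26, lost without day 1 pool 3 (adjusted p = 0.0513), day 17 pool 1 (0.0547) or day 17 pool 2 (0.0683)).

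Of the 5 measured B and plasma cell markers, 2 rose, 0 fell and 3 did not pass (3 and 0 adjusted over the list alone), with median 1.76, camera adjusted p = 0.00677, and adjusted p = 0.621 with an estimated correlation. The 2 were TNFRSF17 and JCHAIN, the chain that joins polymeric immunoglobulins (1.76 ± 0.22), from 8532 ± 2523 to 27914 ± 252. PIGR, which carries polymeric immunoglobulin across epithelium, rose by 1.42 ± 0.16, and on day 17 its signal stood at 62.7% of the brightest endogenous probe set. Of the acute phase and defence genes, 2 rose and 3 fell of 18 (4 and 5 adjusted over the list alone, 1 and 11 with E. coli scaling, median -0.32, camera adjusted p = 0.797), and with E. coli scaling camera's direction turned up (0.0179) although 1 rose and 11 fell (median -1.20). CFB, complement factor B, fell (-2.90 ± 0.47, dim on day 17), and the chemokine CXCL2 fell (-1.05 ± 0.24, lost without day 1 pool 2 (adjusted p = 0.0536), day 17 pool 2 (0.0583) or day 17 pool 3 (0.0732)). GZMH, a granzyme, rose by 2.38 ± 0.39. For T and NK cell markers 1 rose and 0 fell of 8 (median 0.57, camera adjusted p = 0.0554). Adjusted over the list alone these were 1 and 0. E. coli scaling gave 1 and 1 (median -0.30, camera up, adjusted p = 7.93e-06). The list shifted without day 1 pool 1 (adjusted p = 0.00233).

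Of the 7 measured milk protein genes, 5 rose, 0 fell and 2 did not pass (7 and 0 adjusted over the list alone, 0 and 0 with E. coli scaling), with median 0.80, camera adjusted p = 0.000209, and adjusted p = 0.621 with an estimated correlation, and all 7 log2 differences lay between 0.75 and 0.84. The median was 0.06 after quantile normalization (camera adjusted p = 0.428) and reversed to -0.08 with E. coli scaling, and the E. coli controls themselves were brighter by a median of 0.89. CSN1S1 rose by 0.84 ± 0.12, lost after quantile normalization (adjusted p = 0.49) or with E. coli scaling (0.759, log2 -0.03). WAP rose by 0.83 ± 0.23, lost without any 1 of 7 arrays (adjusted p from 0.0504 to 0.108). It was also lost after quantile normalization (0.911), with no filter (0.0596), without an intensity trend (0.0761) or with E. coli scaling (0.86, log2 -0.04). On day 17 CSN1S1 stood at 87.2% and WAP at 84.6% of the brightest endogenous probe set, and saturation could not be tested directly. The 20 brightest had a mean with SD 0.009 log2 on day 17, 0.22 on day 1 and 0.15 on day -17, as a ceiling could give. Of the 10 milk fat globule genes, 6 rose, 0 fell and 4 did not pass (7 and 0 adjusted over the list alone, 0 and 1 with E. coli scaling), with median 0.83, camera adjusted p = 5.68e-05, and adjusted p = 0.461 with an estimated correlation and a median of -0.04 with E. coli scaling. RAB18, a lipid droplet GTPase, rose by 0.99 ± 0.19, lost with E. coli scaling (adjusted p = 0.615, log2 0.11), and CIDEA, a lipid droplet protein, by 1.78 ± 0.45, lost without day 1 pool 2 (adjusted p = 0.0785), day 1 pool 3 (0.0604), day 17 pool 1 (0.085), day 17 pool 2 (0.0748) or day 17 pool 3 (0.0689) and with E. coli scaling (0.0944, log2 0.91).

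Of the 27 genes of fatty acid and triglyceride synthesis, 11 rose, 1 fell and 15 did not pass (12 and 3 adjusted over the list alone, 1 and 11 with E. coli scaling), with median 0.56, camera adjusted p = 0.0107, and adjusted p = 0.73 with an estimated correlation. The shift was lost after quantile normalization (adjusted p = 0.0746) or by fry (0.0526), and the median was -0.31 with E. coli scaling. GPAM, which starts glycerolipid synthesis, rose by 1.53 ± 0.25 and DGAT1, which completes triglycerides, by 1.31 ± 0.26, lost with E. coli scaling (adjusted p = 0.178, log2 0.44). ACOT7, an acyl-CoA thioesterase, fell (-1.08 ± 0.26, lost without day 1 pool 2 (adjusted p = 0.0593), day 1 pool 3 (0.0756), day 17 pool 1 (0.0646) or day 17 pool 3 (0.0669)). Of the 56 ribosomal protein genes, 5 rose, 2 fell and 49 did not pass (9 and 3 adjusted over the list alone, 0 and 56 with E. coli scaling), with median 0.18, camera adjusted p = 0.00294, and adjusted p = 0.822 with an estimated correlation, the opposite direction after quantile normalization (median -0.13) or E. coli scaling (-0.69), and a loss without day 1 pool 1 (adjusted p = 0.153) and by fry (0.393). RPS27 rose by 0.51 ± 0.11, lost without day 17 pool 1 (adjusted p = 0.0556) and after quantile normalization (0.0846), with E. coli scaling (0.00628, log2 -0.37) or with a mean over its probe sets (0.238).

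The remaining lists did not shift between days 1 and 17. For cholesterol synthesis, 1 rose and 2 fell of 12 (2 and 2 adjusted over the list alone, 0 and 8 with E. coli scaling, median 0.08, camera adjusted p = 0.611), with SC5D up (1.12 ± 0.17) and NSDHL down (-1.08 ± 0.23), both enzymes of the late pathway. The other probe set of NSDHL had the opposite sign, and its call was lost with a mean over its probe sets (adjusted p = 0.325), that of SC5D with E. coli scaling (adjusted p = 0.143, log2 0.24). For lactose synthesis, 2 rose and 1 fell of 12 (3 and 1 adjusted over the list alone, 0 and 8 with E. coli scaling, median -0.01, camera adjusted p = 0.611), with a mean of 0.06 against that median, a rise of UGP2 (0.97 ± 0.17, lost with E. coli scaling (adjusted p = 0.615, log2 0.09)) and a fall of HK1 (-0.78 ± 0.13). For amino acid transporters, 1 rose and 1 fell of 14 (1 and 1 adjusted over the list alone, 0 and 9 with E. coli scaling, median 0.10, camera adjusted p = 0.789). Their rise was SLC1A2, a glutamate carrier (1.84 ± 0.41), lost without day 1 pool 3 (adjusted p = 0.0508), day 17 pool 2 (0.0557) or day 17 pool 3 (0.0671) and with E. coli scaling (0.0541, log2 0.97). Their fall was SLC38A1, a glutamine carrier (-1.40 ± 0.36), lost without day 1 pool 2 (adjusted p = 0.0825), day 1 pool 3 (0.0558), day 17 pool 1 (0.0754), day 17 pool 2 (0.0586) or day 17 pool 3 (0.1) and without an intensity trend (0.0516). For ion transport, 2 rose and 0 fell of 9 (2 and 0 adjusted over the list alone, 0 and 5 with E. coli scaling, median 0.25, camera adjusted p = 0.104), with a shift by fry (adjusted p = 0.0446). Its rises were ATP2C2, a Golgi calcium pump (1.50 ± 0.40), lost without day -17 pool 3 (adjusted p = 0.051), day 1 pool 2 (0.0977), day 1 pool 3 (0.0777), day 17 pool 1 (0.101), day 17 pool 2 (0.099) or day 17 pool 3 (0.0692) and without an intensity trend (0.0576) or with E. coli scaling (0.177, log2 0.63), and ORAI1 (0.71 ± 0.17), lost without day 1 pool 2 (adjusted p = 0.0649), day 17 pool 1 (0.0545), day 17 pool 2 (0.0813) or day 17 pool 3 (0.0579) and with E. coli scaling (0.39, log2 -0.16).

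For prolactin and hormone signalling, 3 rose and 1 fell of 16 (median 0.18, camera adjusted p = 0.414). Adjusted over the list alone these were 3 and 2. E. coli scaling gave 1 and 9 (median -0.70, camera up, adjusted p = 0.0179). PTHLH rose and IGFBP5, a binding protein of insulin-like growth factors, fell (-2.93 ± 0.45). For apoptosis and involution, 1 rose and 3 fell of 23 (2 and 3 adjusted over the list alone, 0 and 21 with E. coli scaling, median -0.11, camera adjusted p = 0.414). TGFB3, a growth inhibitor, fell (-1.15 ± 0.18) and MMP2, a matrix protease, fell (-1.82 ± 0.37, lost without day 17 pool 1 (adjusted p = 0.0509)). SQSTM1, an autophagy receptor, rose (0.66 ± 0.12), lost with E. coli scaling (adjusted p = 0.162, log2 -0.21). For mitochondrial energy, 0 rose and 3 fell of 36 (0 and 3 adjusted over the list alone, 0 and 36 with E. coli scaling, median -0.14, camera adjusted p = 0.119), with a shift without day 1 pool 1 (adjusted p = 0.0112) and with E. coli scaling (3.87e-05, median -1.02) and a fall of COX7A2, a cytochrome oxidase subunit (-0.69 ± 0.14). For cell junctions, 1 rose and 1 fell of 8 (median -0.38, camera adjusted p = 0.61). Adjusted over the list alone these were 1 and 1, and with E. coli scaling 0 and 4. For luminal epithelium, 1 rose and 0 fell of 17 (median 0.18, camera adjusted p = 0.61). Adjusted over the list alone these were 0 and 0. E. coli scaling gave 0 and 7 (median -0.70, camera up, adjusted p = 0.0179). For myoepithelium and smooth muscle, 1 rose and 1 fell of 12 (median 0.16, camera adjusted p = 0.477). Adjusted over the list alone these were 2 and 2, and with E. coli scaling 1 and 7. For adipocyte markers, 0 rose and 0 fell of 11 (0 and 0 adjusted over the list alone, 0 and 5 with E. coli scaling, median -0.79, camera adjusted p = 0.385). For macrophage markers, 0 rose and 0 fell of 11 (0 and 0 adjusted over the list alone, 0 and 11 with E. coli scaling, median -0.52, camera adjusted p = 0.147), with a shift without day 1 pool 3 (adjusted p = 0.00589). For interferon response, 0 rose and 0 fell of 18 (median 0.31, camera adjusted p = 0.119). Adjusted over the list alone these were 0 and 0. E. coli scaling gave 0 and 7 (median -0.56, camera up, adjusted p = 0.000359). The list shifted without day 1 pool 1 (adjusted p = 0.0336). For MHC class II, 1 rose and 0 fell of 9 (1 and 0 adjusted over the list alone, 0 and 7 with E. coli scaling, median 0.04, camera adjusted p = 0.477). No gene passed among 4 neutrophil, 4 erythrocyte, 2 skeletal muscle and 1 skin keratinocyte markers, and adjusted over the list alone only 1 erythrocyte marker did. The actin control had a 3' to 5' ratio of 15.3 ± 0.68 (SD) on day 17 against 9.01 ± 0.59 on day 1, and GAPDH had 1.91 ± 0.12 against 2.29 ± 0.04.

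The third comparison asked how the gland in established lactation differed from that of late pregnancy. ACSL6 rose by 8.86 ± 0.29 (n = 3 pools per day, 378-fold with a pseudocount of 16), from a dim signal of 79.0 ± 34.6 (SD) to 34197 ± 159.9, and the mucin MUC4, also dim on day -17, by 7.65 ± 0.26 (122-fold). WAP rose by 6.24 ± 0.23, to 70329.6 ± 825, near the top of the arrays' range. Saturation there could not be tested and would make its rise, measured as 75.6-fold, too small. E. coli scaling went the other way and lowered its log2 difference by 1.30, so the fold is not a lower bound. The adipocyte genes RBP4 and LIPE, hormone-sensitive lipase, fell (-6.33 ± 0.88 and -5.70 ± 1.36). VCAN, a large matrix proteoglycan, fell by 2.69 ± 0.23.

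By limma, 7223 of 15519 probe sets (46.5%) changed, 3367 higher and 3856 lower on day 17. Among these, 3809 changed at least 2-fold and 3667 had no gene symbol here. The 3 values of one day all lay above those of the other for 59.0% of the tested probe sets, where chance gives 10%. Centring each array on its median gave 4373 higher and 2852 lower, and E. coli scaling gave 471 and 12685. Of 25 gene lists, 10 shifted by camera, 8 up and 2 down. With an estimated correlation 0 shifted, while 3 had an unadjusted p under 0.05, and fry gave 14.

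The other largest changes were rises of C7H6orf52 (8.24 ± 0.60) and EDDM3B (8.16 ± 0.40) and falls of CES1 (-6.60 ± 0.60) and CA3 (-6.16 ± 0.86). With a pseudocount of 16, the folds were 22.0 for C7H6orf52, 47.7 for EDDM3B, 35.3 for CES1, 55.1 for CA3, 26.0 for RBP4 and 24.1 for LIPE, since each was dim on 1 of the days.

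Of the 7 milk protein genes, 7 rose, 0 fell and 0 did not pass (7 and 0 adjusted over the list alone, 5 and 0 with E. coli scaling), with median 2.56, camera adjusted p = 1.69e-06, and adjusted p = 0.384 with an estimated correlation. Of the 10 milk fat globule genes, 9 rose, 1 fell and 0 did not pass (9 and 1 adjusted over the list alone, 7 and 1 with E. coli scaling), with median 3.02, camera adjusted p = 1.69e-06, and adjusted p = 0.255 with an estimated correlation. The fall was that of VAMP2 (-0.71 ± 0.21), lost without day -17 pool 3 (adjusted p = 0.0807) or day 17 pool 1 (0.0769) and after median centring (0.0538). Of the 12 cholesterol synthesis genes, 10 rose, 0 fell and 2 did not pass (10 and 0 adjusted over the list alone, 7 and 2 with E. coli scaling), with median 1.89, camera adjusted p = 5.31e-06, and adjusted p = 0.384 with an estimated correlation, led by HMGCS1 (3.47 ± 0.28). Of the 27 fatty acid and triglyceride genes, 15 rose, 4 fell and 8 did not pass (15 and 4 adjusted over the list alone, 8 and 14 with E. coli scaling), with median 0.72, camera adjusted p = 0.00332, and adjusted p = 0.502 with an estimated correlation and a median of -0.58 with E. coli scaling. ACSL3 rose most (4.75 ± 0.16). The 4 that fell were DGAT2 (-4.24 ± 0.53) and, named after their values were seen, ME1 (-3.56 ± 0.62), ACSL1 (-2.11 ± 0.38) and IDH1, a cytosolic isocitrate dehydrogenase (-0.46 ± 0.13). Beside them, adipocyte markers had a mean of -2.12 (standard error 0.56) and a median of -1.46. Of 11, 1 rose and 5 fell (1 and 6 adjusted over the list alone, 0 and 10 with E. coli scaling). All day 17 array means lay below all day -17 means. Camera did not call the list (adjusted p = 0.126), but did without day -17 pool 2 (0.0174) and after median centring (0.0487). Among adipocyte markers only FABP4 rose (0.66 ± 0.24), lost without any 1 of 6 arrays (adjusted p from 0.0598 to 0.115). It was also lost after quantile normalization (0.33), with no filter (0.0595), without an intensity trend (0.0752), with the 6 samples alone (0.0526) or with E. coli scaling (0.0328, log2 -0.64).

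Of the 37 genes of the secretory pathway and protein folding, 22 rose, 0 fell and 15 did not pass (23 and 0 adjusted over the list alone, 3 and 26 with E. coli scaling), with median 0.77, camera adjusted p = 3.48e-06, and adjusted p = 0.502 with an estimated correlation and a median of -0.53 with E. coli scaling. CRELD2 rose by 2.18 ± 0.29. Of the 14 amino acid transporters, 8 rose, 1 fell and 5 did not pass (8 and 1 adjusted over the list alone, 1 and 9 with E. coli scaling), with median 0.52, camera adjusted p = 0.0283, and adjusted p = 0.299 with an estimated correlation, a median of -0.78 with E. coli scaling and a loss with a stricter filter (adjusted p = 0.201). SLC6A14 rose by 7.10 ± 0.62 and SLC38A1 fell (-1.27 ± 0.36, lost without day -17 pool 2 (adjusted p = 0.058), day -17 pool 3 (0.0514) or day 17 pool 3 (0.0583)). Of the 9 ion transport genes, 5 rose, 0 fell and 4 did not pass (5 and 0 adjusted over the list alone, 3 and 4 with E. coli scaling), with median 0.92, camera adjusted p = 0.0109, and adjusted p = 0.299 with an estimated correlation and a median of -0.38 with E. coli scaling. SLC34A2 rose by 4.80 ± 0.26. For lactose synthesis, 3 rose and 3 fell of 12 (3 and 3 adjusted over the list alone, 2 and 9 with E. coli scaling, median -0.20, camera adjusted p = 0.962), with a shift up by fry (0.0176) and a mean of 0.20 against that median. B4GALT1 rose by 3.27 ± 0.16 and HK1 fell (-1.32 ± 0.13).

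Of the 23 cell cycle genes, 0 rose, 17 fell and 6 did not pass (0 and 20 adjusted over the list alone, 0 and 23 with E. coli scaling), with median -1.82, camera adjusted p = 6.87e-06, and adjusted p = 0.502 with an estimated correlation, and RRM2 fell most (-2.77 ± 0.45, dim on day 17). That shift was lost with E. coli scaling (adjusted p = 0.0664, median -3.13). Of the 26 fibroblast matrix genes, 0 rose, 15 fell and 11 did not pass (0 and 17 adjusted over the list alone, 0 and 26 with E. coli scaling), with median -1.26, camera adjusted p = 2.57e-05, and adjusted p = 0.502 with an estimated correlation and a loss with E. coli scaling (adjusted p = 0.193, median -2.56). Beside them, for endothelial markers, 1 rose and 2 fell of 12 (0 and 0 adjusted over the list alone, 0 and 12 with E. coli scaling, median -0.17, camera adjusted p = 0.67), with CD34 lower (-1.15 ± 0.32, lost without day 17 pool 1 (adjusted p = 0.0502)) and EGFL7 higher (0.45 ± 0.16), the latter lost without day -17 pool 2 (adjusted p = 0.135), day 17 pool 1 (0.0581), day 17 pool 2 (0.0633) or day 17 pool 3 (0.119) and with no filter (0.0508), with the 6 samples alone (0.0513) or with E. coli scaling (0.000606, log2 -0.85). Of the 56 ribosomal protein genes, 29 rose, 4 fell and 23 did not pass (29 and 4 adjusted over the list alone, 0 and 56 with E. coli scaling), with median 0.36, camera adjusted p = 0.000464, and adjusted p = 0.743 with an estimated correlation, a loss by fry (adjusted p = 0.0702) and the opposite direction after quantile normalization (median -0.24) or E. coli scaling (-0.94). RPS18 rose (0.91 ± 0.16), and on day 17 stood at 99.9% of the brightest endogenous probe set. It went to -0.07 after quantile normalization and -0.39 with E. coli scaling, and 1 of its 2 other probe sets had the opposite sign.

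For macrophage markers, 1 rose and 6 fell of 11 (1 and 6 adjusted over the list alone, 0 and 10 with E. coli scaling, median -0.87, camera adjusted p = 0.197), with a shift with the 6 samples alone (adjusted p = 0.0482). C1QC, a complement chain made by macrophages, fell (-1.41 ± 0.40, lost without day 17 pool 3 (adjusted p = 0.0562)), and CD14 rose (1.19 ± 0.26), lost with E. coli scaling (adjusted p = 0.707, log2 -0.11). For MHC class II, 2 rose and 6 fell of 9 (2 and 6 adjusted over the list alone, 0 and 7 with E. coli scaling, median -0.61, camera adjusted p = 0.235), with SLA-DQB1 down (-1.23 ± 0.23) and SLA-DMA up (1.51 ± 0.20, lost with E. coli scaling (adjusted p = 0.281, log2 0.21)). For B and plasma cell markers, 3 rose and 0 fell of 5 (3 and 0 adjusted over the list alone, 2 and 2 with E. coli scaling, median 1.85, camera adjusted p = 0.22), with a shift with E. coli scaling (adjusted p = 0.000229, median 0.55) or by fry (0.0218) and TNFRSF17 up (3.71 ± 0.40). For T and NK cell markers, 1 rose and 0 fell of 8 (1 and 0 adjusted over the list alone, 0 and 5 with E. coli scaling, median -0.15, camera adjusted p = 0.973), with a mean of 0.02 and an upward test against that median, and with GZMH up (2.01 ± 0.39, lost with E. coli scaling (adjusted p = 0.128, log2 0.71)). For acute phase and defence genes, 8 rose and 5 fell of 18 (median 0.31, camera adjusted p = 0.126). Adjusted over the list alone these were 8 and 5. E. coli scaling gave 6 and 10 (median -0.99, camera up, adjusted p = 6.93e-08). The list shifted with a stricter filter (adjusted p = 0.0211) or by fry (3.53e-05). HP rose by 7.24 ± 0.39, and DEFB1, a defensin, fell (-2.56 ± 0.74, dim on day 17), lost without day -17 pool 1 (adjusted p = 0.0657) and with no filter (0.147, log2 0.90). PGLYRP1 rose (4.49 ± 0.20), alone of 4 neutrophil markers (1 and 0 adjusted over the list alone).

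For luminal epithelium, 4 rose and 4 fell of 17 (median 0.31, camera adjusted p = 0.67). Adjusted over the list alone these were 4 and 4. E. coli scaling gave 1 and 11 (median -0.99, camera up, adjusted p = 0.0078). CLDN3 rose (2.28 ± 0.29). FOXA1 fell (-2.21 ± 0.65), lost without day -17 pool 2 (adjusted p = 0.0696), day -17 pool 3 (0.0707) or day 17 pool 1 (0.0644). For myoepithelium and smooth muscle, 5 rose and 1 fell of 12 (median 0.52, camera adjusted p = 0.126). Adjusted over the list alone these were 5 and 1. E. coli scaling gave 2 and 7 (median -0.78, camera up, adjusted p = 0.0078). The list shifted without day 17 pool 1 (adjusted p = 0.0451) or by fry (0.0109). MYLK rose (4.56 ± 0.98, dim on day -17), and TPM2, a tropomyosin, fell (-1.16 ± 0.24), although 2 of its 3 other probe sets had the opposite sign, and its call was lost with a mean over its probe sets (adjusted p = 0.298). For cell junctions, 1 rose and 1 fell of 8 (1 and 1 adjusted over the list alone, 1 and 6 with E. coli scaling, median -0.70, camera adjusted p = 0.455), with OCLN up (1.85 ± 0.19) and the gap junction protein GJA1 down (-1.44 ± 0.27). For apoptosis and involution, 7 rose and 7 fell of 23 (7 and 8 adjusted over the list alone, 0 and 22 with E. coli scaling, median -0.05, camera adjusted p = 0.868), with MMP2 down (-2.52 ± 0.37). MAP1LC3B, an autophagosome protein, rose (0.89 ± 0.11, -0.41 with E. coli scaling), and its other probe set had the opposite sign. For prolactin and hormone signalling, 4 rose and 5 fell of 16 (4 and 5 adjusted over the list alone, 2 and 12 with E. coli scaling, median -0.28, camera adjusted p = 0.987), with a mean of 0.20 and an upward test against that median, a shift by fry (adjusted p = 0.00865), EGF up (6.36 ± 0.32) and IGFBP5 down (-3.43 ± 0.45). For mitochondrial energy, 10 rose and 4 fell of 36 (10 and 4 adjusted over the list alone, 0 and 36 with E. coli scaling, median 0.05, camera adjusted p = 0.763), with a shift down with E. coli scaling (0.00947, median -1.26) and MDH1, cytosolic malate dehydrogenase, down (-0.91 ± 0.18). NDUFV2 rose (0.95 ± 0.14, -0.35 with E. coli scaling). For interferon response, 1 rose and 0 fell of 18 (0 and 0 adjusted over the list alone, 0 and 13 with E. coli scaling, median 0.11, camera adjusted p = 0.687), with IFI44L up (0.65 ± 0.19), whose 2 other probe sets had the opposite sign and whose call was lost without day -17 pool 2 (adjusted p = 0.0625), day 17 pool 1 (0.0592) or day 17 pool 3 (0.0648) and with E. coli scaling (0.00534, log2 -0.66) or with a mean over its probe sets (0.859). Of 4 erythrocyte markers 0 rose and 2 fell (0 and 3 adjusted over the list alone), HBB at -1.33 ± 0.13, named after its values were seen, and ALAS2 at -2.84 ± 0.98, lost without day -17 pool 1 (adjusted p = 0.119), day -17 pool 3 (0.0564), day 17 pool 2 (0.118) or day 17 pool 3 (0.095) and without an intensity trend (0.0526). Of 2 skeletal muscle markers TNNI2 fell (-1.40 ± 0.49, 0 and 1 adjusted over the list alone), lost without day -17 pool 2 (adjusted p = 0.138), day -17 pool 3 (0.0936), day 17 pool 1 (0.119) or day 17 pool 3 (0.0874) and after median centring (0.0588). KRT10, the only skin keratinocyte marker, did not pass (0.08 ± 0.18, -1.22 with E. coli scaling). The actin control had a 3' to 5' ratio of 15.3 ± 0.68 (SD) on day 17 against 7.15 ± 0.13 on day -17, GAPDH 1.91 ± 0.12 against 2.83 ± 0.39, and EF1a 1.88 ± 0.10 against 1.33 ± 0.09 (1.43 ± 0.12 on day 1).

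Probe sets that had moved by day 1 mostly stood on the same side on day 17. Of the 1860 that rose from day -17 to day 1, 1555 were also higher on day 17 than on day -17, including WAP and HMGCS1, and 9 were lower. Of the 1876 that fell, 1505 were also lower on day 17, including DGAT2, and 8 were higher. Independent lists of these sizes would share 404 and 466 among the 15519. Between the consecutive steps, 336 probe sets rose in both (131 for independent lists) and 179 fell in both (124), while 118 rose and then fell (123), including MANF, and 101 fell and then rose (132). These comparisons share a day's arrays, and in 20 simulations of unchanged groups on the same layout a mean of 0 were shared, which sets no level for the overlaps, since at most 1 probe set was called in any. Part of any excess may come from the shared arrays. The covariance of the log2 differences across probe sets was 0.695 for the comparisons that share day -17 (0.0595 simulated, correlations 0.823 and 0.502), and 0.101 for the consecutive steps (-0.0579 simulated, correlations 0.206 and -0.492).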

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

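All tests of explanations in this part were chosen only after the results were seen.

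Control probe sets, which the comparisons left out, differed between days. The median of the 21 E. coli hybridization control probe sets was higher by 1.28 (log2) on day 17 than on day -17, and all 21 were higher, as were all 36 B. subtilis control probe sets (median 0.97). A larger scaling factor on the day 17 arrays may explain this: the dimmest 2399 of the endogenous probe sets also rose, by a median of 0.84. More control transcript added to these arrays stays open: the mean of the 20 brightest endogenous probe sets rose by 1.19 (standard error 0.085), but all 20 of the brightest on day 17 were called rises and 5 stood for milk protein or milk fat globule genes, so lactation itself would raise that mean. A larger share of milk transcripts in the labelled RNA stays open too: the milk protein list held 0.419% of the summed signal on day -17 and 2.29% on day 17, where its signals were near the top of the range.

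Probe sets for ribosomal RNA were also outside the comparisons. The 28S probe sets were higher by 2.67 and 2.05 on day 1 and by 3.63 and 3.01 on day 17 than on day -17, and 1 for 18S by 2.14 and 3.27. Scaling alone was argued against, because the rising rRNA probe sets exceeded the E. coli controls by a median of 1.99. A larger share of ribosomal RNA in the labelled material could be a cause, but only 3 of the 5 rRNA probe sets rose beyond the controls, and the other probe set for 18S fell by 1.97 to day 1 and stood at -1.46 on day 17 against day -17, which leaves it open. Lactation was not tested as an explanation of this pattern.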

How the results depend on the processing

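Scaling to the E. coli controls was chosen after seeing the data, and the other alternatives before. The number of arrays and the brightness of a probe set over background limited what was detected.

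That scaling gave 7085, 11114 and 13156 changed probe sets for day 1 against day -17, day 17 against day 1 and day 17 against day -17, and 13280 over the 3 days, because it lowers every log2 difference in a comparison by the same amount. A minimum fold of 2 gave 1592, 820 and 3809, and a single probe set per gene 1455, 941 and 2700, both by counting fewer. The counts without 1 array ranged from 2110 to 4424, from 1049 to 2109 and from 5887 to 7639, and over the 3 days from 5410 to 7719. The pool number as a fixed block gave 4496, 2743 and 7825, and as a random block 4463, 2792 and 7804 (consensus correlation 0.125). For day 17 against day 1, samples with the same number had correlations of 0.0960 to 0.107 and others -0.0768 to -0.0268, so the numbers hint at pairs. The block ended the shift of MHC class II for day 1 against day -17. For day 17 against day 1 it ended the call of MYLK (fixed only, 0.0619) and brought those of RBP4 (0.0391 fixed, 0.0419 random) and HBB (0.0496 fixed, 0.0360 random). It changed no other call of a list or named gene.

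Of the gene lists, 0, 0 and 0 shifted with an estimated correlation by limma's camera (5, 1 and 3 at an unadjusted p under 0.05, and 8, 5 and 14 by fry). For day 17 against day 1, scaling to the E. coli controls gave 13 lists. Camera's direction for ribosomal proteins turned from up to down after quantile normalization (list mean minus that of the other genes -0.19, -0.12 and -0.31). It also turned down with scaling to the E. coli controls, although that difference, which a common shift leaves alone, was 0.11, 0.17 and 0.29. With this scaling camera's direction turned up for acute phase genes on day 17 against day 1 (difference -0.11) and down for mitochondrial genes on day 17 against day -17 (0.10). Camera compares moderated statistics, in which a common shift weighs more on genes with small standard errors. Lists called only with this scaling moved in these statistics, not in log2 against the other genes. On day 17 against day -17 the mean z of ribosomal proteins went from 1.66 to -4.71 and that of the other genes from 0.0034 to -3.42. Without that scaling, fry's direction was up for lactose synthesis on day 17 against day -17 (0.23), against camera's.

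Of named genes called higher, scaling to the E. coli controls turned these negative. For day 1 against day -17 it was RPS12 (-0.052). For day 17 against day 1 it was CSN1S1 (-0.034), WAP (-0.044), B4GALT1 (-0.26), ORAI1 (-0.16), RPS27 (-0.37), RPL5 (-0.41, and -0.032 after quantile normalization), SQSTM1 (-0.21), OCLN (-0.082), EPCAM (-0.22) and SLA-DMA (-0.11). For day 17 against day -17 it was RPS18 (-0.39, and -0.073 after quantile normalization), NDUFV2 (-0.35), MAP1LC3B (-0.41), FABP4 (-0.64), EGFL7 (-0.85), CD14 (-0.11) and IFI44L (-0.66). KRT10, not called before, was then (-1.22). With no filter DEFB1 was 0.90 on day 17 against day -17, from another probe set.

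Left-out arrays aside, list results were the same in 888 cases, weaker in 51, stronger in 21 and reversed in 9. List labels follow tests, so a median that changed sign may count as same. For named genes these were 1798, 109, 14 and 22. A left-out array weakened 19 list and 230 gene results and strengthened 14 and 4.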

Other observations

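The gene families and the tests of the fibroblast pattern in this part were chosen only after the results were seen, while the counts of sample splits were planned.

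In 9 added families, each represented by its measured members, N-glycosylation shifted up to day 1: 12 rose and 2 fell of 21 measured (median log2 difference 0.81, camera adjusted p = 0.00843, adjusted p = 0.398 with an estimated correlation), with scaling to the E. coli controls giving 6 up and 6 down (median 0.38). Subunits of the vacuolar ATPase shifted up to day 1, where 6 rose and 0 fell of 13 measured (median log2 difference 0.36, camera adjusted p = 0.0107, adjusted p = 0.398 with an estimated correlation), with a median of -0.06 under that scaling (1 up and 1 down), and on day 17 against day -17, where 10 rose and 0 fell of 13 measured (median log2 difference 0.53, camera adjusted p = 0.00564, adjusted p = 0.428 with an estimated correlation), with -0.77 (0 up and 10 down). Rab GTPases shifted up on day 17 against day -17: 13 rose and 4 fell of 25 measured (median log2 difference 0.48, camera adjusted p = 0.0279, adjusted p = 0.203 with an estimated correlation), with -0.82 under that scaling (2 up and 18 down).

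From day 1 to day 17, 4 families shifted down. For proteasome subunits, 0 rose and 4 fell of 33 (median -0.16, camera adjusted p = 0.0098, adjusted p = 0.538 with an estimated correlation). For heat shock proteins, 1 rose and 6 fell of 22 (median -0.32, camera adjusted p = 0.0098, adjusted p = 0.315 with an estimated correlation). For aminoacyl-tRNA synthetases, 0 rose and 3 fell of 18 (median -0.34, camera adjusted p = 0.0302, adjusted p = 0.515 with an estimated correlation). For N-glycosylation, 0 rose and 4 fell of 21 (median -0.27, camera adjusted p = 0.0305, adjusted p = 0.515 with an estimated correlation). With E. coli scaling these had 0 up and 33, 17, 18 and 20 down. Translation initiation factors, chemokines and complement components did not shift in any comparison.

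Fibroblast matrix genes were lower as a list on day 17 than on day -17, with a median of -1.26. A smaller share of all or some non-epithelial cells stays open. Such lists moved apart, but errors without a spread over genes cannot decide it. The fibroblast mean less theirs changed by -0.98 ± 0.13 for endothelium, -0.60 ± 0.20 for macrophages and 0.92 ± 0.32 for adipocytes. For T and NK cells it was -1.22 ± 0.25, and for B and plasma cells -2.53 ± 0.54. Adipocyte and macrophage means were lower too (-2.12 and -0.61). An effect of brightness on scaling is argued against: 0% of 10000 random lists matched on signal had as low a median. The lowest 2.5% lay below -0.24. Fewer fibroblasts, and lower expression in them, may each explain it and were not told apart. With E. coli scaling, the median was -2.56 and all 26 were lower. Camera's call ended (adjusted p = 0.193), but the list's difference from other genes stayed -1.17. Its mean z went from -2.58 to -4.10, the others' from 0.03 to -3.43.

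Splits of the 6 samples into 3 and 3 number 10 for each comparison, the real one included, too few for a share under 0.05. The real split was the only 1 of 10 with as many changed probe sets: 3736 for day 1 against day -17 (highest other 3), 2116 for day 17 against day 1 (highest other 0) and 7223 for day 17 against day -17 (highest other 0). Over the 3 days, 1 of 100 splits, the real one, gave as many as 7028, so chance assignment of samples to days can be excluded for that count. The highest other count, 3022, came from a split with 2 samples out of their day.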
